A study of Homo sapiens with 2 samples.

How the data were processed

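CUT&Tag was performed on the enzalutamide-resistant C4-2B line with 1 antibody per library, H3K4me1 and H3K27ac, from 100000 cells per sample and 14 cycles of PCR. The labels name a rabbit anti-mouse secondary antibody for both libraries, while the primary antibodies are sold as rabbit antibodies, and any effect on the signal was not tested. Per the submitters' processing notes, BWA and MACS2 were used with the hg38 genome. The notes give no version or setting and do not say whether a background library was given to the peak caller. The data used were the deposited peak lists, 1 per library. The deposited fold enrichment is a ratio of the signal at the peak summit to the local background, by the authors' peak caller. The deposited significance values are -log10 p and -log10 q at the summit, and the highest q was 0.0499 for H3K27ac and 0.0488 for H3K4me1. The deposited score of each peak is 10 times -log10 q rounded down, for all but a few peaks. No replicate, parental line or background library was among the samples, so no test between conditions was made and no p-value for a difference between conditions is given. For gene lists, chances among random lists are given.

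Peaks on chromosomes 1 to 22 and X were used, 64784 of 64850 for H3K27ac and 139511 of 139692 for H3K4me1, and no peaks within a list overlapped. Total sequencing depth is unknown from the peak lists. The depth behind each peak was recovered from the values instead, a step chosen after the data were seen. If k fragments pile up at a summit over a background of lambda, the deposited fold is (k + 1) / (lambda + 1) and the deposited p is the Poisson chance of more than k fragments. Solving both gave a whole number k for 99.94% of H3K27ac peaks (all but 39) and 99.98% of H3K4me1 peaks (all but 34), within 0.001 in -log10 p or a relative 0.0001. The recovered background was most often 0.447 fragments for H3K27ac (18.0% of peaks) and 0.453 for H3K4me1 (17.0%). It rose with the library's own peak signal within 10 kb, the peak itself included (Spearman 0.903 and 0.935 across peaks, which are not independent replicates). The median background went from 0.447 fragments in the least to 6.13 in the most densely marked surroundings for H3K27ac, and from 0.453 to 4.82 for H3K4me1. The median ratio of fold enrichment to pileup fell from 0.790 to 0.143 and from 0.758 to 0.177. For this reason pileups are given beside folds, with exact Poisson 95% intervals.

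Genes came from a RefSeq table for GRCh38, with 19974 protein-coding genes on the chromosomes used. The table gave no strand, exons or sequence. Either end of a gene therefore stood in for its transcription start, the number of RefSeq transcripts for the number of starts, and location was given as gene end, gene body or outside genes. A peak within 2.5 kb of an end was at a gene end, and the others were distal. Motif searches for 10 consensus motifs and an alternative with only the 5 prime ends of genes needed sequence or strand and were not run. No list of problem regions was used to remove peaks.

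Peaks overlapped when they shared at least 1 bp. The overlap was set beside 100 rotations of the peaks along each chromosome, after stretches over 1 Mb without a peak were removed in place of assembly gaps, which left 2631.85 Mb. Local shifts of 20 to 200 kb were a second form of random placement. Shares have exact Clopper-Pearson 95% intervals, which cover counting error only. Super-enhancer-like regions were called from H3K27ac peaks, because the usual algorithm needs reads, which were not used here. The 18182 peaks lying wholly within 2.5 kb of a gene end were excluded and the rest joined over gaps of at most 12.5 kb. Regions were ranked by the sum over peaks of fold enrichment times length, with the threshold where the scaled rank curve has slope 1. A gene was near a region when an end lay within 50 kb of it, and had a mark when a peak lay within 1 kb of an end.

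The 17 gene lists (390 members, 387 distinct genes, all found in the table) covered androgen response, prostate lineage factors and coactivators, luminal, basal and neuroendocrine genes, glucocorticoid receptor targets, Wnt, androgen synthesis, cell cycle, epithelial mesenchymal transition, growth factor and PI3K signalling, chromatin coactivators, lipid synthesis, housekeeping, blood, stromal and other organ markers. Another list also held 3 members of the androgen response list and 1 each of the lineage, glucocorticoid and lipid lists. The lists were written before the data were examined, as were the comparisons and the rule for named genes. Each count was placed as a percentile among 10000 random lists of the same size, matched on decile of gene density within 100 kb and on tertile of transcript number, with ties counted at their midpoint. The random lists were drawn gene by gene. Neighbouring members of a list that share a region or a peak were counted separately, which can make a percentile more extreme. Genes named were those nearest to the 10 highest-ranked regions, up to 4 members of each list near a region, up to 2 members of each list without H3K27ac in alphabetical order, a fixed set that included FOXA1, HOXB13, KLK3, TMPRSS2, NR3C1 and MYC, those nearest to the 5 widest H3K4me1 peaks, and the 5 with the highest H3K27ac fold at an end. This rule gave 103 genes.

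Alternatives set before the data were examined were a minimum -log10 q of 5, the 20000 highest-scoring peaks of each list, an overlap of at least 50%, gene ends within 1 kb, stitching at 5 or 20 kb, no exclusion at gene ends, ranking by summed fold or summed length, 20 or 100 kb to a region, and random lists not matched or matched also on H3K27ac. Chosen after the data were seen were a minimum pileup of 10 fragments, ranking by pileup times length, matching on gene length, the count of genes with H3K4me1 but no H3K27ac, and the counts near chromosome ends. The methods were tested on simulated data. The pileup was recovered for 54566 of 54566 and 126629 of 126629 simulated pairs of pileup and background, after pairs with a weak p or a pileup not above background were left out. The simulated values came from the same formula that the recovery inverts, so this tests the solving and not the assumed formula. Of 20000 simulated peaks with 12000 placed on H3K4me1, 12215 overlapped it, and 8000 peaks placed at random gave 215 overlaps against 243 in their rotations. All 100 planted clusters of strong peaks were called, but 138 of the 238 called regions were scattered peaks, since the slope rule always calls some regions. Lists of 24 genes with 10 members planted near regions passed the upper bound of the central 95% of random lists in 200 of 200 cases, and random lists in 5 of 200. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.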

Results

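C4-2B is a castration-resistant human prostate cancer line derived from LNCaP, and the cells profiled here had been kept for at least 6 months in enzalutamide, an antiandrogen drug. Histone marks were mapped by CUT&Tag, in which an antibody directs a transposase to cut and tag DNA at the marked nucleosomes. The 2 libraries, made from 100000 cells each, mapped H3K4me1, a mark of enhancers and of promoter flanks, and H3K27ac, a mark of active enhancers and promoters. The study concerned super-enhancers, large clusters of active enhancers, in these resistant cells. With 1 library per antibody and no sensitive cells or background library among the samples, all values describe the resistant line, and no difference between conditions was tested. The H3K27ac list held 64784 peaks on chromosomes 1 to 22 and X, covering 24.4 Mb, with a median width of 250 bp and a median fold enrichment of 6.05. The H3K4me1 list held 139511 peaks covering 37.8 Mb, with a median width of 207 bp and a median fold enrichment of 7.001. The number of fragments piled up at each peak summit, recovered from the deposited values, had a median of 13 for H3K27ac (range 4 to 540) and 18 for H3K4me1 (range 4 to 480). A summit pileup below 10 fragments was found at 38.5% of H3K27ac peaks and 22.3% of H3K4me1 peaks. Intervals after pileups are exact Poisson 95% intervals, those after shares are exact Clopper-Pearson 95% intervals, and both cover counting error only. Pileup counts are called fragments here, but the labels do not say whether fragments or single reads were counted, or whether PCR duplicates were removed. Duplicates left in would make the Poisson intervals too narrow. Gene ends stand for promoters below, because the gene table used gave no strand, so a peak at the far end of a gene counts as well. Starts inside the listed span of a gene were not examined, so a gene without a mark at its ends may carry it at such a start.

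The comparison of the 2 marks asked which regions carried both, as active enhancers usually do. Both marks lay at the ends of the prostate genes KLK3, TMPRSS2, HOXB13 and FOXA1 and at ELF3, CASZ1 and the tight junction gene CLDN4. H3K27ac was not called at the ends of EHF, FGFR3 or AGR2, whose H3K4me1 summits held 22, 60 and 18 fragments. Across the genome, 47665 of the H3K27ac peaks (73.6%, 73.2 to 73.9) overlapped an H3K4me1 peak, against a mean of 2213 (range 2019 to 2379) in 100 rotations of the peaks along their chromosomes. Local shifts gave a mean of 3467. Neither form of random placement separates both marks at the same site from signal common to both libraries for another reason. No background library was available to do so. In the other direction, 53183 H3K4me1 peaks (38.1%, 37.9 to 38.4) overlapped H3K27ac, against a mean of 2368. H3K27ac peaks within 2.5 kb of the end of a protein-coding gene numbered 18786 (29.0%), which was 3.77 times the mean of the rotations, and 83.1% (82.6 to 83.6) of them overlapped H3K4me1. They were also wider and deeper than the distal peaks, with a median of 493.5 bp and 42 fragments against 216 bp and 10 fragments. Of the 45998 distal H3K27ac peaks, 69.7% (69.3 to 70.1) overlapped H3K4me1. H3K4me1 peaks lay at gene ends in 21.97% of cases (30657 peaks, 3.13 times the rotations). Of the 108854 distal H3K4me1 peaks, 33166 (30.5%) overlapped a called H3K27ac peak and 75688 (69.5%) did not. The H3K27ac list was shorter and its summits shallower, so H3K27ac is not shown to be absent from the latter. Among the 20000 highest-scoring peaks of each list, at all locations, the overlap was 53.3% of H3K27ac and 54.2% of H3K4me1 peaks. Peaks inside protein-coding genes but away from their ends made up 45.7% of the H3K27ac list and 46.9% of the H3K4me1 list, and peaks outside all genes 16.9% and 21.1%. The share of H3K27ac peaks with H3K4me1 rose with depth, from 37.9% at 4 to 7 fragments to 96.1% at 35 to 540 fragments. At gene ends the same 4 groups of peaks gave 35.2%, 61.6%, 83.8% and 95.2%, and away from them 38.2%, 70.2%, 94.2% and 97.6%.

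**Figure D1:**
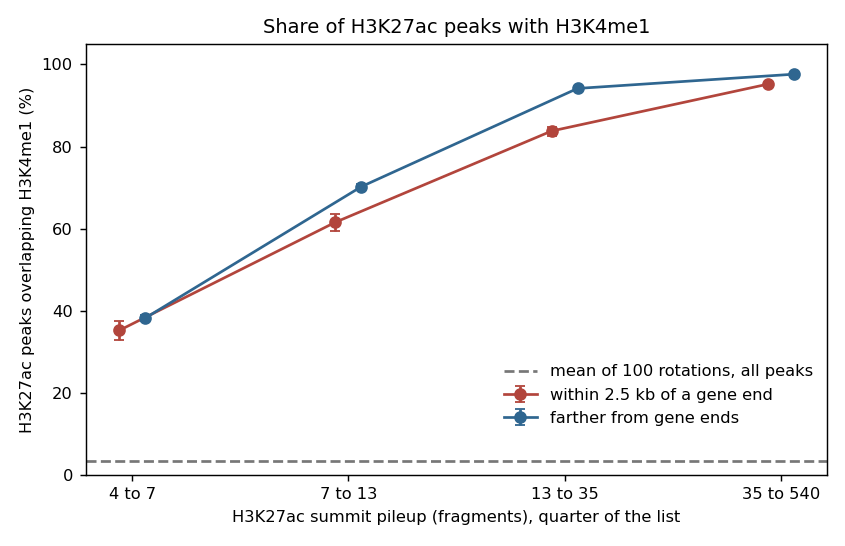
Share of H3K27ac peaks that overlap an H3K4me1 peak (vertical axis, percent) by summit pileup in fragments (horizontal axis, 4 groups of equal size over the whole list), for peaks within 2.5 kb of a gene end and for peaks farther away; bars are exact 95% binomial intervals and the dashed line is the mean of 100 rotations. The share is 35.2% at gene ends and 38.2% elsewhere for the weakest peaks, and above 95% in both locations for the strongest.

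The H3K27ac clusters that ranked highest lay over CASZ1, MCF2L and ANKRD11. The H3K27ac peaks not wholly within 2.5 kb of a gene end joined into 25233 stitched regions, of which 1324 were called super-enhancer-like. CASZ1, which encodes a zinc-finger transcription factor, ranked 1, with a region of 163909 bp at chromosome 1, 10640559 to 10804467. This region held 79 H3K4me1 peaks and 51 H3K27ac peaks, of which 48 were not wholly within 2.5 kb of a gene end and entered the ranking. Rank 2 lay in MCF2L (chromosome 13, 112926245 to 113015148), rank 3 over ANKRD11 and LOC128462377 (chromosome 16, 89314354 to 89454206) and rank 4 over C13orf46 and RASA3 (chromosome 13, 113919751 to 114016035). Rank 5 lay inside NEDD4L, a ubiquitin ligase gene (chromosome 18, 58168530 to 58322280), with 29 H3K27ac and 65 H3K4me1 peaks. INPP5A held rank 6 (chromosome 10, 132546642 to 132652129). Rank 7 overlapped EEFSEC (chromosome 3, 128323221 to 128435635), 43.8 kb from GATA2, a zinc-finger transcription factor gene. LOC124905135 held rank 8, in a region that also covers the let-7b host gene MIRLET7BHG (chromosome 22, 46035682 to 46130147). Ranks 9 and 10 lay at LRIG1, a regulator of growth factor receptors (chromosome 3, 66401866 to 66493161), and at CCNK and CCDC85C (chromosome 14, 99508431 to 99597149). These 10 regions were also called in each of the 8 alternative ways of calling regions. Of the 10, 5 lay within 5 Mb of a chromosome end (50%, 18.7 to 81.3), against 13.4% of all stitched regions. The 1324 regions had a median length of 18254 bp and a median of 4 H3K27ac peaks that entered the ranking. Of these regions, 226 rested on 1 such peak, so not every called region is a cluster. The 1324 covered 31.2 Mb, and 1001 of them (75.6%) overlapped a protein-coding gene. All 1324 held an H3K4me1 peak (99.7 to 100%), against 76.1% (75.5 to 76.6) of the other 23909 regions, whose median length was 350 bp. By length, H3K4me1 peaks covered 11.2% of the super-enhancer-like regions and 12.05% of the others. Peak by peak, 79.5% (78.5 to 80.4) of the H3K27ac peaks in super-enhancer-like regions overlapped H3K4me1, against 68.0% (67.5 to 68.5) in the other regions. The regions were selected by fold enrichment times length, and the peaks were not matched on depth or width. Because the overlap rises with depth, this difference may follow from the selection. The call depended on the ranking value and on the peaks used. Ranking by pileup in place of fold enrichment called 986 regions that matched 785 of the 1324 (59.3%), and keeping the peaks at gene ends matched 582 (44.0%).

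**Figure D2:**
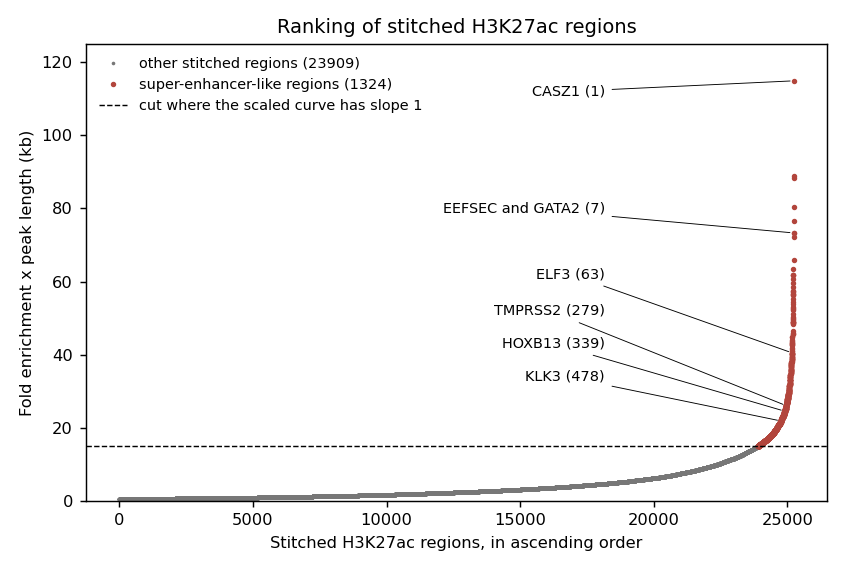
Stitched H3K27ac regions in ascending order (horizontal axis) against the sum over their peaks of fold enrichment times peak length, in kb (vertical axis), with the 1324 super-enhancer-like regions in red and the dashed line at the threshold. CASZ1 lies at the top, and the labelled prostate genes ELF3, TMPRSS2, HOXB13 and KLK3 hold ranks 63, 279, 339 and 478.

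**Figure D3:**
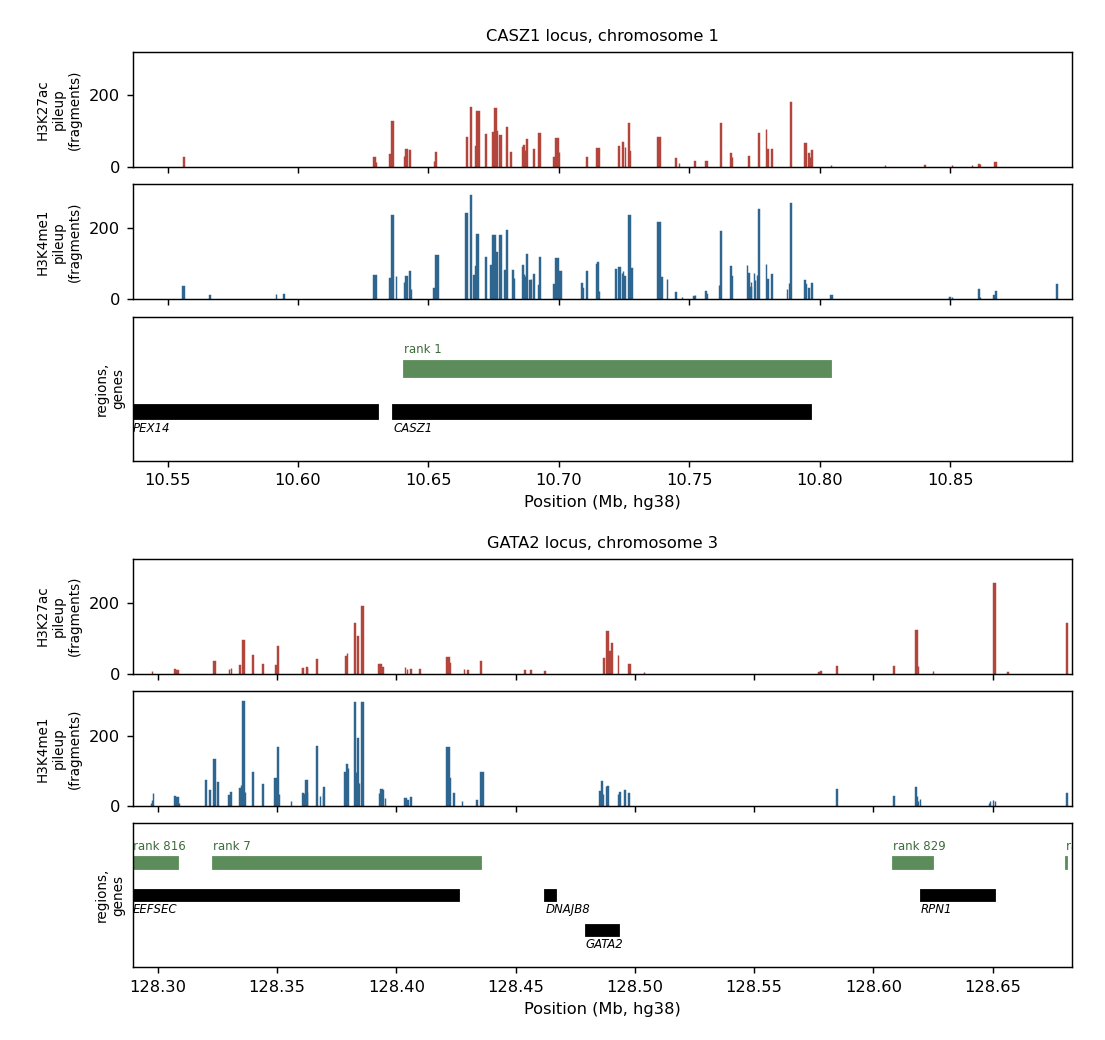
H3K27ac (red) and H3K4me1 (blue) peaks at the CASZ1 and GATA2 loci, with height as summit pileup in fragments and position in Mb on hg38, above the super-enhancer-like regions with their ranks (green) and the genes (black). Peaks of both marks fill CASZ1, and the region of rank 7 covers part of EEFSEC beside GATA2.

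Most androgen response targets carried both marks. Of these 27 genes, 23 had H3K27ac and 26 had H3K4me1 at a gene end, against medians of 18 and 19 in random lists of matched genes (percentiles 98.6 and 99.95 of 10000 lists). Matched also on gene length, the H3K27ac percentile was 97.2, inside the central 95% of random lists. KLK3, which encodes prostate-specific antigen, had 106 H3K27ac fragments (86.8 to 128) at its end. A super-enhancer-like region of rank 478 (chromosome 19, 50835853 to 50858431) overlapped KLK3. It held 11 H3K27ac peaks, 9 of them not wholly within 2.5 kb of a gene end, and 12 H3K4me1 peaks. KLK2, 15.01 kb from that region, had 117 H3K27ac fragments (96.8 to 140) and 214 H3K4me1 fragments (186 to 245). TMPRSS2, an androgen-driven protease gene, had 193 H3K27ac fragments (167 to 222), with a region of rank 279 (chromosome 21, 41520742 to 41536792) 12.6 kb away. KLK4 and ADAM7 had no H3K27ac peak in the narrow window used for gene ends, and had 53 and 64 H3K4me1 fragments there. Inside KLK4, however, lay H3K27ac peaks of 107 fragments (50909100 to 50909753) and 42 fragments (50908291 to 50908852). Both lay outside that window but within 2.5 kb of an end, so KLK4 did not lack H3K27ac as a gene. Near regions the list was within the range of matched lists, with 5 members (TMPRSS2, MPHOSPH9, KLK2, KLK3 and KLK4) against a median of 3 (percentile 81.1). KLK2, KLK3 and KLK4 were all counted through the region of rank 478. MYC had 47 H3K27ac fragments (34.5 to 62.5) and lay 51.0 kb from a region, just outside the 50 kb limit.

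**Figure D4:**
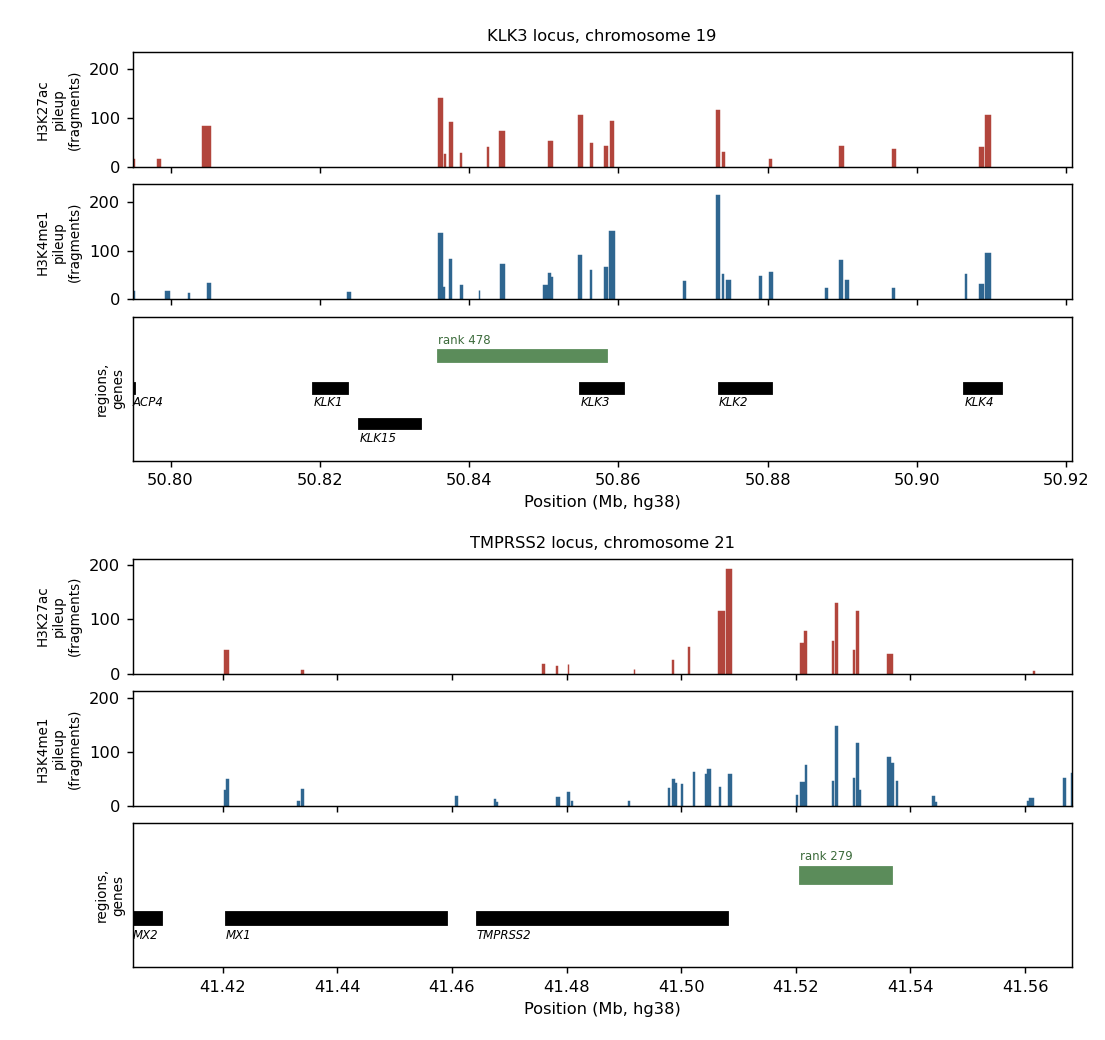
H3K27ac (red) and H3K4me1 (blue) peaks at the KLK3 and TMPRSS2 loci, with height as summit pileup in fragments and position in Mb on hg38, above the super-enhancer-like regions with their ranks (green) and the genes (black). The region of rank 478 overlaps KLK3, and that of rank 279 lies outside TMPRSS2.

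Most prostate lineage transcription factors and luminal markers carried both marks, while most basal markers did not. Of 22 lineage transcription factors and coactivators, 17 had H3K27ac (median of matched lists 13, percentile 95.8, inside the central 95%) and 19 had H3K4me1 at a gene end (median 14, percentile 98.5). HOXB13 had 111 H3K27ac fragments (91.3 to 134) and lay 4.17 kb from the region of rank 339 (chromosome 17, 48732920 to 48757130). ELF3, an epithelial ETS factor, had 144 H3K27ac fragments (121 to 170) and 237 H3K4me1 fragments (208 to 269), 17.4 kb from the region of rank 63. FOXA1, a pioneer factor gene, had 74 H3K27ac fragments (58.1 to 92.9). FOXA1 had no region within 50 kb, although 4 of the 10 alternative settings placed one there. GATA2, ELF3, HOXB13 and GRHL2 were the 4 members near a region (median 2, percentile 87.1). This percentile ran from 74.0 to 99.98 over the settings. HOXA10 was among the 3 members with neither mark at an end. Among 22 luminal markers, 18 had H3K27ac (median 13, percentile 98.8, but 97.2 among lists not matched) and 20 had H3K4me1 (median 14, percentile 99.9), with 227 H3K27ac fragments (198 to 259) at CLDN4 and 178 (153 to 206) at KRT8. The listed spans of KRT8 and KRT18 overlap, and KRT18 had the same H3K27ac pileup and fold enrichment (13.7) as KRT8. The 178 fragments therefore appear to come from a peak that counted for both genes. CLDN3, CLDN4, KRT8 and KRT18 lay near regions (median 2, percentile 81.5), KRT8 and KRT18 through the same region. Of 20 basal markers, 7 had H3K27ac (median 13, percentile 0.75) and 9 had H3K4me1 (median 13, percentile 2.76, inside the central 95%, but 2.42 and outside it with matching also on gene length), and CAV1, CAV2, FAT2 and TRIM29 had neither. FAT2, TRIM29 and ITGA6 were the 3 basal markers near a region (median 2, percentile 64.7).

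Neuroendocrine genes, which mark a cell state that some treated prostate cancers take on, had H3K4me1 more often than H3K27ac at their ends. Of 24 such genes, 9 had H3K27ac at an end (median of matched lists 14, percentile 2.65), while 18 had H3K4me1 (median 15, percentile 89.2). Both counts lay inside the central 95% of random lists, and the H3K27ac percentile was 5.45 with matching also on gene length and 0.875, outside that range, among lists not matched. ENO2, a neuronal enolase gene, had 92 H3K27ac and 195 H3K4me1 fragments, and SYP, the synaptophysin gene, 38 and 38. CHGA, the chromogranin A gene, had no H3K27ac and 7 H3K4me1 fragments (2.81 to 14.4). CEACAM5 had neither mark. CHGA, ENO2 and SYP lay near regions (median 2, percentile 65.4), CHGA 10.9 kb from rank 42, and SYP in 6 of the 10 alternative settings.

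Targets of the glucocorticoid receptor were near super-enhancer-like regions more often than in most matched lists, while the receptor gene NR3C1 was not marked. NR3C1 had neither mark at its ends and 0 H3K27ac and 5 H3K4me1 peaks within 50 kb. Of the 20 genes, 15 had H3K27ac (median 12, percentile 94.0) and 19 had H3K4me1 (median 13, percentile 99.97) at an end, and 6 lay near a region (median 2, percentile 99.1). The region of rank 46 (chromosome 11, 114067201 to 114180825) lay inside ZBTB16, a zinc-finger factor gene, 7.49 kb from an end, and held 26 H3K27ac and 43 H3K4me1 peaks. NFKBIA, CDKN1C and GADD45B lay near the regions of ranks 113, 156 and 415, and had 90, 12 and 28 H3K27ac fragments at their ends. KLF9 and TSC22D3 were the other two, named after their values were seen, and TSC22D3 lay near a region in 5 of the 10 alternative settings. The percentile lay between 98.2 and 99.99 over these settings, with 4 to 13 members. It was 97.3 among lists not matched and 95.3, with 4 members, without regions within 5 Mb of a chromosome end, both inside the central 95% of random lists. CRISPLD2 had H3K4me1 (16 fragments) without H3K27ac.

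Wnt, cell cycle, growth factor, coactivator and lipid genes carried both marks at most of their members. Of 26 Wnt pathway genes, 24 had H3K27ac and 24 had H3K4me1 (percentiles 99.9 and 99.8), with WNT7B (54 H3K27ac and 197 H3K4me1 fragments, rank 141) and ZNRF3 (rank 562) among the 5 near regions (median 3, percentile 87.4). TCF7 had neither mark. Of 26 cell cycle genes, 24 had H3K27ac and 25 had H3K4me1 (percentiles 99.96 and 99.99), and 7 lay near regions (median 3, percentile 96.5, but 98.1 and above the central 95% with matching also on gene length), among them CDC6 and TOP2A, which share the region of rank 27, and MCM5. CDKN1A, an inhibitor of the cell cycle, had neither mark at its ends, with 8 H3K27ac and 15 H3K4me1 peaks in the gene and 50 kb around it. Of 24 growth factor receptor and PI3K genes, 21 had H3K27ac and 23 had H3K4me1 (percentiles 99.1 and 99.8), with 265 H3K27ac fragments (234 to 299) at AKT2. AKT1, AKT2 and EGFR were among the 7 near regions (median 3, percentile 98.6). That percentile fell to 38.4, with 1 member, when only peaks of at least 10 fragments were used, and EGFR was near a region in 5 of the 10 alternative settings. All 24 chromatin coactivators had both marks (percentiles 99.995 and 100), with 129 H3K27ac fragments at SMARCA4 and 134 at KDM6A, and 5 lay near regions (median 3, percentile 79.4), SMARCA4 among them. Of 23 lipid and cholesterol synthesis genes, 21 had each mark (percentiles 99.6 and 98.9), with 185 H3K27ac fragments (159 to 214) at SREBF1, a regulator of lipid synthesis. The 6 lipid genes near regions (median 3, percentile 92.6) included SREBF1 (rank 45), FDFT1 (rank 150) and FASN, which was so in 5 of the 10 alternative settings. The lipid percentile ran from 21.97 to 99.2 over the settings, with 1 member at a minimum -log10 q of 5. FDFT1 and ACACB had neither mark at their ends. Within these genes and 50 kb around them lay 13 and 15 H3K27ac peaks and 15 and 18 H3K4me1 peaks.

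Genes of androgen synthesis and inactivation were among the least marked at their ends. Of these 20 genes, 4 had H3K27ac (median 12, percentile 0.02) and 6 had H3K4me1 (median 13, percentile 0.13). The steroid enzyme genes AKR1C2, AKR1C3 and CYP17A1 had neither at their ends. Within these genes and 50 kb around them lay 1, 1 and 3 H3K27ac peaks and 10, 9 and 7 H3K4me1 peaks. CYP17A1, 47.1 kb from rank 540, was the 1 member near a region (median 2, percentile 22.5). Genes of epithelial mesenchymal transition and stemness lay inside the random range, with 13 of 23 carrying H3K27ac and 14 H3K4me1 (percentiles 39.2 and 38.5). POU5F1 and ITGA5 were among the 3 members near regions (median 3, percentile 59.7), and ALDH1A1 had neither mark.

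Housekeeping genes and markers of other cell types served as a reference. All 22 housekeeping genes had H3K27ac and 21 had H3K4me1 (percentiles 100 and 99.97), with 157 H3K27ac fragments at PPIA, and 6 lay near regions (median 3, percentile 96.4), including ACTB and B2M. Of 22 blood and immune markers, 5 had H3K27ac and 6 had H3K4me1 (percentiles 0 and 0.01), and CD3D had neither. Of 22 stromal and endothelial markers, 3 had H3K27ac and 4 had H3K4me1 (percentiles 0 and 0), and CDH5 and CLDN5 had neither. Of 23 markers of liver and other organs, 5 had H3K27ac and 6 had H3K4me1 (percentiles 0.015 and 0.005), and AFP had neither. Each of these 3 lists had 1 member near a region (percentiles 8.18, 11.97 and 10.9), CD14, DES and MBP, which were so in 4, 2 and 6 of the 10 alternative settings. Over the settings these percentiles ran from 2.39 to 31.1 for blood, 0.52 to 65.5 for stromal and 3.21 to 67.1 for other organ markers, so the blood and stromal lists fell below the central 95% in some. Percentiles of 0 and 100 are the extremes that 10000 lists can give. With the settings reported, 68 percentiles were computed, and more under the alternatives, so some would be extreme by chance. With lists matched also on H3K27ac, the H3K4me1 count lay above the central 95% for the androgen response, glucocorticoid and neuroendocrine lists (percentiles 99.4, 99.7 and 99.9) and inside it for the other 14.

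**Figure D5:**
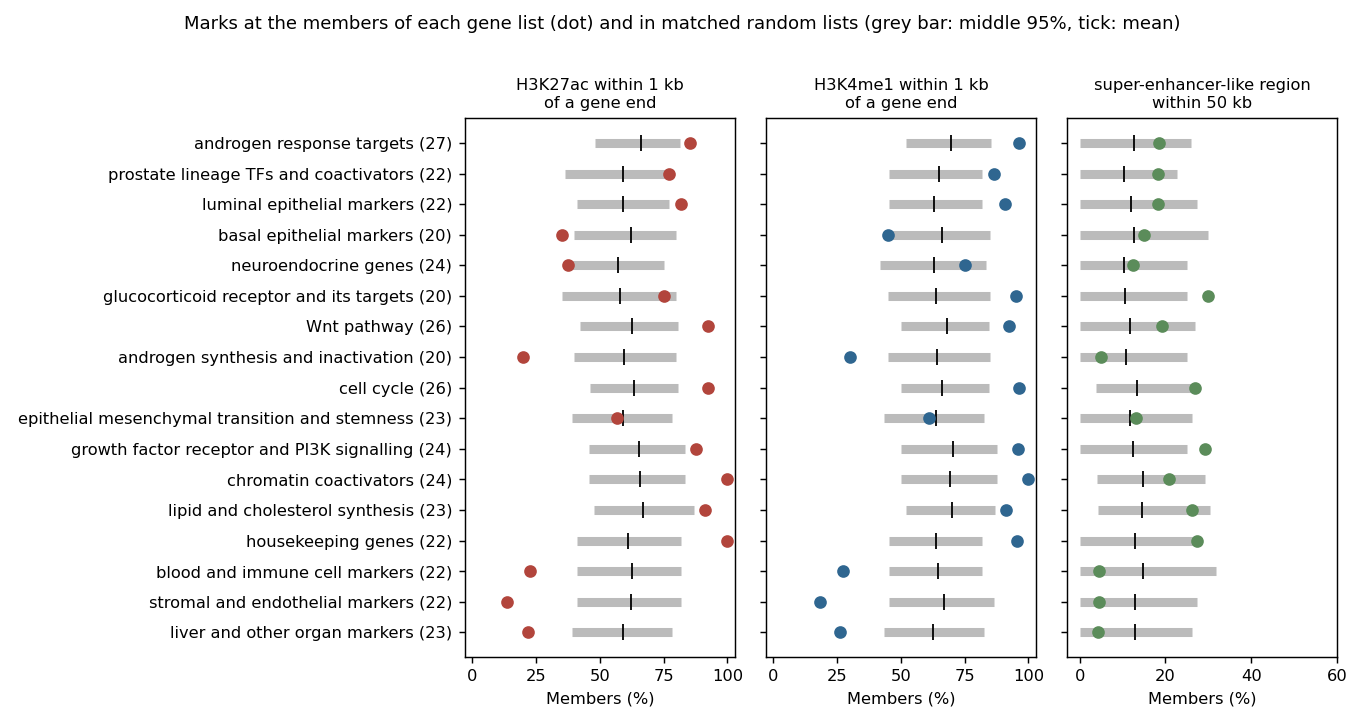
Share of the members of each of the 17 lists (number of genes in parentheses; horizontal axis, percent) with H3K27ac within 1 kb of a gene end, with H3K4me1 there, and with a super-enhancer-like region within 50 kb of a gene end; grey bars span the middle 95% of 10000 matched random lists and ticks give their means. Housekeeping and coactivator genes lie above the grey bars for both marks at gene ends, and blood, stromal and other organ markers lie below them.

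The highest H3K27ac enrichment at a gene end was at PDXDC1, with a fold enrichment of 47.7 and 179 fragments (154 to 207). GSTA4, ZSCAN30, POM121C and HBS1L followed with fold enrichments of 35.0, 35.0, 33.3 and 31.5. The widest H3K4me1 peak lay at TIMM22 (chromosome 17, 1004049 to 1006794), 2746 bp wide with 264 fragments. Those nearest to XAB2, NDUFS7, MCF2L and ZBTB42 were 2625, 2583, 2566 and 2520 bp wide, and all 5 overlapped an H3K27ac peak. Of all 19974 protein-coding genes, 12435 (62.3%) had H3K27ac at an end, 13106 (65.6%) had H3K4me1, 11756 (58.9%) had both, and 2686 (13.4%) lay near a super-enhancer-like region.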

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

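The minimum of 10 fragments, the ranking by pileup and the matching on gene length were chosen after the data were seen. Of 42 alternative values of the main counts, 29 stayed within 1.5 times the count reported and 13 did not. With -log10 q of at least 5 there were 42351 H3K27ac peaks and 1765 genes near super-enhancer-like regions. With at least 10 fragments there were 39824 H3K27ac peaks, 21311 distal H3K27ac peaks with H3K4me1, 684 regions and 1400 genes near them. Among the 20000 highest-scoring peaks of each list, 10650 H3K27ac peaks overlapped H3K4me1 (53.3%) and 10842 the reverse. Stitching at 5 kb gave 3942 regions and 5621 genes, and keeping peaks at gene ends gave 4998 genes. Counting genes within 20 kb gave 1541 and within 100 kb 4123. By construction, the filters leave fewer peaks, the distances change which genes count, and peaks kept at gene ends place regions at genes. For stitching at 5 kb the cause was not tested. The share of H3K27ac peaks with H3K4me1 was 88.1% with -log10 q of at least 5, 88.7% with at least 10 fragments and 63.5% with an overlap of at least 50%.

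Of the 66 named genes near a region, 21 stayed so in all 10 alternative settings, among them CASZ1, ELF3, HOXB13, KLK2, KLK3, TMPRSS2, CDKN1C, GADD45B, CHGA and WNT7B, and 45 did not. For the list counts near regions, 97 of 170 alternative values stayed within 1.5 times, as did 46 of 51 percentiles under other matching. That bound is loose for high percentiles, since a fall from 99.1 to 97.3, into the central 95%, stays within it. The glucocorticoid list had percentiles from 98.2 to 99.99 over the settings for regions, but 97.3 among lists not matched and 95.3 without regions near chromosome ends, both inside the central 95% of random lists, and the growth factor list ran from 38.4 to 98.6. Other ranges were 47.6 to 95.9 for the androgen response, 43.4 to 99.4 for luminal, 67.4 to 98.5 for Wnt, 76.9 to 99.7 for cell cycle, 10.7 to 92.9 for coactivator, 58.1 to 99.9 for housekeeping, 12.4 to 92.3 for basal, 20.4 to 85.8 for neuroendocrine, 8.69 to 49.6 for androgen synthesis and 17.98 to 75.95 for mesenchymal genes. Matching on H3K27ac fixes the H3K27ac count of a list, so it says nothing about that count. No paired analysis was possible because each antibody had 1 library. The 5 prime end alternative and the motif comparisons with their 3 alternatives were not run, for lack of strand and sequence. With 38.5% of H3K27ac peaks below 10 fragments, a mark not called at a gene is not shown to be absent.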

Other observations

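The ranking of regions by pileup and the tests in this part were chosen after the results were seen, except those of weak H3K4me1 at neuroendocrine genes and of regions near chromosome ends, which were set before their own values were computed. The loci named in this and the next paragraph were also chosen after their values were seen. Ranked by pileup times length, the leading H3K27ac region covered MALAT1, a gene for an abundant nuclear noncoding RNA (chromosome 11, 65468958 to 65508591, 13 peaks). Rank 4 covered NEAT1, which makes the noncoding RNA of paraspeckles (65416472 to 65455537, 15 peaks). LOC124905135 and CASZ1 held ranks 2 and 3, and PWWP2B and NFIX ranks 5 and 6. The deepest H3K27ac summit, 540 fragments, lay in the NEAT1 region at 65418425 to 65419322, where the fold enrichment was 4.72. Other deep summits lay at HNRNPF (432 fragments) and at KMT2E (428 fragments), a gene of the KMT2 family.

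In the neuroendocrine list, 10 genes had H3K4me1 without H3K27ac at their ends. These genes, among them CHGA, FOXA2, INSM1, PEG10, PROX1 and SOX2, had 5 to 44 H3K4me1 fragments (median 14). PEG10 had 44 (32.0 to 59.1), FOXA2 25 (16.2 to 36.9) and SOX2 13 (6.92 to 22.2). Genome-wide, 1350 genes (6.76%) had H3K4me1 alone, with a median of 13 fragments. The glucocorticoid list had 4 such genes and the androgen, blood and other organ lists 3 each. The lineage, luminal, basal, androgen synthesis, mesenchymal, growth factor and stromal lists had 2 each, the Wnt and cell cycle lists 1 each, and the coactivator, lipid and housekeeping lists 0.

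Among the H3K27ac peaks with 35 to 540 fragments, 78.5% (75.1 to 81.6, 499 of 636) of those without H3K4me1 lay at gene ends, against 63.7% (63.0 to 64.5) of the 15560 with it.

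The 10 neuroendocrine genes with H3K4me1 alone, against a median of 2 in lists matched on gene density and transcript number (percentile 100, the highest 10000 lists can give), were weighed against chance and weak signal. The exact chance that any of 17 such lists would be as extreme in any of the 4 readouts was 0.0372%, which argues against chance among these lists and readouts alone. The readout of H3K4me1 without H3K27ac was itself chosen after the data were seen, and this value does not cover that choice. Lists matched on H3K4me1 pileup at the gene ends had a median of 4 (percentile 99.9), which argues against weak H3K4me1 as the whole cause, although 55.7% of genes with under 10 fragments lacked H3K27ac. In 5.48% of 10000 draws at least 1 of 17 random lists reached that percentile in any of the 4 readouts, so weak H3K4me1 and chance together stay open. A hypothesis is that these genes may be held in a primed, inactive state, which stays untested, since H3K27me3, expression and sensitive cells were not analysed here.

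The 6 glucocorticoid receptor targets near super-enhancer-like regions (percentile 99.1) were weighed in the same way. Lists matched also on having H3K27ac at a gene end gave percentile 98.5, above the central 95% of random lists. This value was not corrected for the 17 lists compared, so it does not decide whether the presence of H3K27ac at an end is the whole cause. The strength of H3K27ac was not matched, so a higher activity of these genes stays open. Super-enhancer-like regions lay within 5 Mb of a chromosome end in 20.8% (18.6 to 23.1) of cases, against 13.4% (13.01 to 13.86) of stitched regions, and without them 4 members remained (percentile 95.3), so regions near chromosome ends may contribute. At least 1 of 17 random lists reached this percentile in 11.2% of 10000 draws, so chance among the lists stays open. Binding of the glucocorticoid receptor to these regions was not analysed here, and NR3C1 itself carried no mark at its ends.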
